A study of Mus musculus with 12 samples.

How the data were processed

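RNA was measured on 12 Illumina bead arrays, on which short DNA probes attached to beads bind labelled copies of the RNA and the bound label is read as light. Each array held 1 sample of mouse lung cells carrying the integrin CD11c, and 100 ng of total RNA per sample was copied into cRNA labelled with biotin, per the labels. The samples formed 4 groups of 3 by genotype and exposure.

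The first of the deposited tables holds the scanned intensity of 45281 probes per array, exported with GenomeStudio (version not given per the labels). No scaling between arrays was visible in these values, since the median signal differed between arrays. Whether a background had been subtracted cannot be told from those medians. Beside each intensity column the deposited table gives a detection p-value per probe, under the header Detection Pval. From the values, these moved in steps of 1 in 936, the resolution of a comparison with negative control beads. The matrix of processed values from the authors is on a log2 scale and, judged from the values, quantile-normalized, with a column median of 3.12 on every array. It holds 24952 probes, exactly those with a detection p under 0.05 on at least 1 array, and each of its columns ranked its probes like the intensities of its own array (rank correlation 1, against at most 0.909 with any other array).

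The tests used the intensities. Background correction and quantile normalization were done with neqc of limma 3.58.1 in R 4.3.3, with the background taken from the detection p-values and an offset of 16, giving log2 intensities. Probes with a detection p under 0.05 on at least 3 of 12 arrays were kept (17346 probes). Gene symbols came from the annotation of the array, in which 20501 probes carried 1 symbol and 11 carried several. For each symbol the probe with the highest mean over all arrays was used, and probes without a single symbol stayed as features of their own. This left 12380 features, 9809 with a symbol and 2571 without. Gene order was taken from the mouse genome build GRCm38.p6 for 9793 features.

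limma fitted 1 model with a mean per group to all 12 arrays (8 residual degrees of freedom, 6.86 prior degrees of freedom). The 5 comparisons were nCB against PBS in each genotype, knockout against wild type under each exposure, and the genotype by exposure interaction, the difference between the nCB effects of both genotypes. All tests were two-sided. A feature was called when its Benjamini-Hochberg adjusted p within a comparison was under 0.05, and an adjusted p in the text is of this kind unless it is said to belong to a list. Values are log2 differences ± the SE from limma, or folds computed from them. With 3 arrays against 3, an exact permutation test cannot give a p under 0.1, so single genes were tested only through limma, which pools the spread across genes.

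Where none of the probes of a gene was detected on any array of a group, the fold is a bound ("at least"). On each array of that group, the gene was set to the lowest log2 intensity among detected probes, or to its own value if higher.

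The 37 gene lists (643 genes) were written before the data were examined, as were the model, the filter, the comparisons, the rule for named genes and most alternatives. Of these lists, 36 had measured members. Each was tested with camera of limma, which asks whether the members of a list shifted against all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 36 lists. The same test with an estimated correlation was run beside it. Members were also counted after adjustment over all features and adjusted over the list alone.

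Named genes follow a fixed rule. It takes up to 12 higher and 12 lower genes per comparison with the largest change among called genes with 1 symbol whose 3 against 3 values did not overlap, or at least 5 per direction. It adds up to 4 members with the smallest p per list, every gene past the interaction test where 10 or fewer pass, and Mir22 or its host transcript, Hdac4, Jun, Fos, Il6, Il1b, Il23a, Mmp12, Mmp9, Cxcl1, Cxcl5, Ccl17, Spp1 and Hmox1 always. Genes outside the rule are said to be chosen after their values were seen. Cxcl5, Spp1 and the Mir22 host transcript had no listed probe, and Il6 and Il23a were detected on too few arrays (2 and 1 of 12), so none of these was tested.

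The mean intensity per array ran from 156 to 218 and 31.4% to 35.0% of probes were detected. The number of arrays limits the precision. In a test on simulated data with 50 changed genes per size, 86% to 98% of changes of 1 log2 unit and 30% to 44% of changes of 0.5 were recovered in the 4 comparisons of groups. For the interaction, 64% and 20% were recovered, and 2.92% to 8.50% of simulated calls were false. The simulated noise was independent between features and held no array effects, so rates in the real data can differ.

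Equal replicate numbers did not pair the arrays: after removing group means, 5 of 18 pairs with the same number correlated above 0.1 (range −0.297 to 0.223), so no block entered the model. Alternatives to the normalization, probe filter, probe choice, variance prior, array weights, samples in the model, replicate block, fold minimum and array set were run. Sequence matches to the seed of the microRNA were not tested, since no sequences of untranslated regions were used here.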

Results

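Lung cells carrying CD11c, an integrin subunit found on alveolar macrophages and dendritic cells, were profiled from wild-type mice and from mice lacking Mir22, the gene of the microRNA miR-22. The labels call them antigen-presenting cells, isolated with AutoMACS, an instrument that separates cells tagged with magnetic beads. The mice had received nCB, nanoparticulate carbon black, or phosphate-buffered saline (PBS) as reference, with a labelled exposure of 1 month starting at 2 months of age. The labelled age was 4 months for all samples, and the time between exposure and isolation was not stated. Each of the 4 groups held 3 arrays. No probe was listed for Mir22 or its host transcript, so a check of the genotype labels on the deleted gene was not possible. The labels do not say whether the arrays of a group came from separate animals, so errors and p-values measure the spread between these samples.

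Mean intensity ran from 156 (knockout PBS 2) to 218 (wild-type PBS 2), and 14215 to 15849 probes (31.4% to 35.0%) were detected per array. The number of arrays limits the precision of every comparison. Between arrays of the same group, log2 intensities correlated at 0.987 to 0.993 across probes. Exposure separated the arrays along the first principal component, which carried 52.0% of the variance and placed PBS arrays between −25.3 and −22.6 and nCB arrays between 17.9 and 29.2. The second carried 12.7% and placed wild-type arrays between 4.73 and 17.6 and knockout arrays between −19.5 and 1.63.

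The first comparison asked how carbon black changed the cells of wild-type lungs. Single chemokines, complement C1q chains and matrix proteases were among the genes that rose strongly. Ccl7, a chemokine that attracts monocytes, was 50.4-fold higher with nCB (log2 5.66 ± 0.18, n = 3 per group, limma adjusted p = 2.28e-11), though only 1 of 3 PBS arrays detected it. The 3 chains of C1q, which opens the classical complement pathway, rose by 20.4-fold (C1qa), 23.3-fold (C1qb) and 25.1-fold (C1qc). Mmp12, the elastase of macrophages, rose by 4.00 ± 0.31 log2 units and Mmp14, a membrane-bound collagenase, by 4.17 ± 0.18. Npy, Arg1 and Ccl12 were undetected in PBS and were at least 16.9-fold, 10.5-fold and 10.4-fold higher. Cidec, a protein of lipid droplets, fell by 3.13 log2 units, as did Krt79 (−2.92), Hr (−2.95) and Acaa1b, a peroxisomal thiolase (−3.24). In all, 1099 of 12380 features rose and 1141 fell, and the groups did not overlap for 34.1% of features against 10% by chance.

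Chemokines outside the neutrophil-attracting group rose together in wild-type cells. Of 16 measured, 12 rose and 1 fell, with the same counts adjusted over the list alone (median log2 1.97, list adjusted p = 2.73e-13, and 0.0384 with an estimated correlation). Ccl9 rose by 3.24 log2 units, Cxcl16 by 3.01 and Ccl17 by 2.44, while Cx3cl1 changed by −1.53. Matrix proteases and their inhibitors also rose in 12 of 17 measured and fell in 1, again unchanged over the list alone (median 1.24, list adjusted p = 3.74e-11, and 0.0384 with an estimated correlation). Among them Timp1 rose by 2.06 and Ctsk by 1.85, and Timp3 changed by −1.05. Interferon response genes rose in 15 of 19 and fell in none, by either adjustment (median 0.86, list adjusted p = 7.24e-11, and 0.0384 with an estimated correlation). Ifi205 rose by 2.01 and Ifit2 by 1.42, and Cxcl10 was at least 2.41-fold higher. Cx3cl1, Timp3, Pparg, Zfp36 and Apoc1 lie outside the rule for named genes in this comparison and were chosen after their values were seen.

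Markers of different cell types moved apart with nCB in wild-type samples. Markers of monocytes and interstitial macrophages rose in 8 of 14 and fell in none (8 and 1 adjusted over the list alone; list adjusted p = 2.05e-07, and 0.0384 with an estimated correlation). They included the C1q chains and Apoe, a lipid carrier (+2.11). Alveolar macrophage markers fell in 9 of 14 and rose in 1 (10 and 1 adjusted over the list alone; median −0.79, list adjusted p = 1.14e-06). With an estimated correlation the adjusted p was 0.052. Cidec, Krt79, Il18 (−1.70) and Pparg (−1.01), the transcription factor that maintains these cells, fell, while Ctsk, a cathepsin also counted among the proteases, rose. The other probe of Il18 did not follow (+0.08). Markers of conventional dendritic cells rose in 7 of 15 and fell in 1, with the same counts over the list alone (list adjusted p = 7.46e-04, and adjusted p = 0.263 with an estimated correlation). Examples were Itgae (+2.57), Ccl17 and Kit (+1.17), against Batf3 (−0.55). The call for Batf3 was lost without wild-type PBS 1 (adjusted p = 0.148), PBS 2 (0.0961), nCB 2 (0.0778) or nCB 3 (0.0927). B cell markers fell in 2 of 8 (6 over the list alone; list adjusted p = 0.0198, and adjusted p = 0.263 with an estimated correlation). This shift was lost without wild-type PBS 1 (adjusted p = 0.0693) or wild-type nCB 3 (adjusted p = 0.0618). Genes of neutrophils rose in 3 of 12 and fell in 3 (list adjusted p = 0.197).

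Stress and activation lists rose as well in wild-type cells. The p53 and DNA damage list rose in 6 of 15 and fell in none (8 and 0 over the list alone; list adjusted p = 1.46e-04, and 0.0384 with an estimated correlation), with Gadd45a (+1.27), Mdm2 (+0.95) and Cdkn1a (+0.89). The unfolded protein response rose in 6 of 15 and fell in 1, by either adjustment (list adjusted p = 0.00324, and 0.0384 with an estimated correlation), with Trib3 (+2.31), Asns (+2.24) and Ddit3 (+1.44). NF-kB feedback genes rose in 8 of 15 and fell in 2 (9 and 2 over the list alone; list adjusted p = 0.00136, and 0.0384 with an estimated correlation), with Socs3 (+1.80), Traf1 (+1.24) and Zfp36 (−0.81). Ligands that stimulate or inhibit T cells rose in 5 of 10 and fell in none (6 and 0 over the list alone; median 0.44, or 0.32 with undetected genes at their bound). Their list adjusted p was 0.00171, and 0.0384 with an estimated correlation, with Cd86 (+1.94) and Cd40 (+1.51). Glycolysis and hypoxia genes rose in 5 of 13 and fell in 1 (7 and 1 over the list alone; list adjusted p = 9.80e-04, and 0.0479 with an estimated correlation), with the glucose transporter gene Slc2a1 (+1.59) and Pgam1 (+1.14).

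Lists of lipid handling, lysosome and antioxidant defence rose with the preset correlation only. Lipid-associated macrophage genes rose in 8 of 15 and fell in 3 (8 and 5 over the list alone; list adjusted p = 0.00324, and adjusted p = 0.052 with an estimated correlation). The lipid receptor gene Trem2 (+2.62), Il7r (+2.41), the scavenger receptor gene Msr1 (+2.23) and Gpnmb (+1.97) rose and Apoc1 (−1.52) fell. Lysosomal genes rose in 9 of 21 and fell in none (12 and 1 over the list alone; list adjusted p = 4.78e-04, and adjusted p = 0.0894 with an estimated correlation), led by Cd63 (+2.76). NRF2 targets rose in 4 of 14 and fell in 1 (6 and 1 over the list alone; list adjusted p = 0.0245, and adjusted p = 0.0894 with an estimated correlation), with Slc7a11 (+2.34), Srxn1 (+1.05) and Hmox1 (+0.93 ± 0.19). Of the 2 further probes of Slc7a11, 1 did not follow (−0.06). Of the other genes named in advance, Fos changed by −1.13 (adjusted p = 0.00479), while Hdac4 (−0.39, 0.113), Jun (−0.53, 0.0592), Il1b (+0.29, 0.518), Mmp9 (+0.36, 0.236) and Cxcl1 (+0.63, 0.0669) did not pass, each with its adjusted p. Cxcl1 lay near background in wild-type PBS samples, which limits the size given. With median scaling in place of quantile normalization, 531 features rose and 754 fell.

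The second comparison asked the same of knockout cells. Ccl7, undetected in knockout PBS, was at least 33.9-fold higher with nCB, and C1qb rose 20.9-fold (log2 4.38 ± 0.21, n = 3 per group, limma). Fstl1, a secreted glycoprotein, rose by 4.34 ± 0.26 and Pdpn, a mucin-like membrane glycoprotein, by 4.23 ± 0.21, with Fstl1 detected on 2 of 3 PBS arrays. Mmp14 (+3.71), Mmp12 (+3.45 ± 0.31), the creatine transporter gene Slc6a8 (+3.70) and Ccl17 (+2.29) rose. Itgad was at least 6.93-fold lower, Hr changed by −3.19, Gal by −3.11 and Cidec by −2.72. The immediate early genes Egr1 (−2.22), Fos (−1.84, adjusted p = 9.32e-05) and Jun (−1.16, adjusted p = 3.98e-04) fell. Hdac4, which encodes a class IIa histone deacetylase, rose by 0.81 ± 0.16 (adjusted p = 0.00247), a call lost with median scaling (adjusted p = 0.0510). In all, 1076 features rose and 902 fell, and the groups did not overlap for 30.5% of features against 10% by chance. With median scaling 497 features rose and 300 fell.

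Proteases, chemokines and monocyte markers rose with nCB in knockout cells. Matrix proteases rose in 13 of 17 and fell in 1, by either adjustment (median 1.00, list adjusted p = 1.30e-10, and 0.0469 with an estimated correlation). Other chemokines rose in 9 of 16 and fell in 1 (10 and 1 over the list alone; median 1.20, list adjusted p = 1.11e-07, and adjusted p = 0.0704 with an estimated correlation). Monocyte and interstitial macrophage markers rose in 8 of 14 and fell in none, by either adjustment (list adjusted p = 2.00e-06, and 0.0469 with an estimated correlation), beside alveolar macrophage markers that fell in 7 of 14 and rose in 1 (8 and 2 over the list alone; median −0.61, list adjusted p = 0.00115, and adjusted p = 0.173 with an estimated correlation). Interferon response genes rose in 8 of 19 and fell in none (9 and 0 over the list alone; median 0.38, or 0.30 with undetected genes at their bound). Their list adjusted p was 4.59e-04, and the adjusted p was 0.127 with an estimated correlation. Lysosomal genes rose in 11 of 21 and fell in 1 (13 and 1 over the list alone; list adjusted p = 5.18e-06, and adjusted p = 0.0551 with an estimated correlation). Neutrophil genes rose in 6 of 12 and fell in none, by either adjustment (list adjusted p = 0.00191, and adjusted p = 0.127 with an estimated correlation), with Chil1 (+2.13) and Lcn2 (+2.00). Their interaction with genotype did not pass (list adjusted p = 0.139).

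Across the 12380 features, the nCB effects of both genotypes correlated at r = 0.80 (jackknife SE over arrays 0.056) and rho = 0.59; features are not independent replicates. Both genotypes called 703 features higher (95.5 expected for independent calls) and 572 lower (83.1 expected), and 2 in opposite directions. A further 963 were called in wild-type cells and 701 in knockout cells without a call in the other genotype, which does not show a difference between them.

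**Figure D1:**
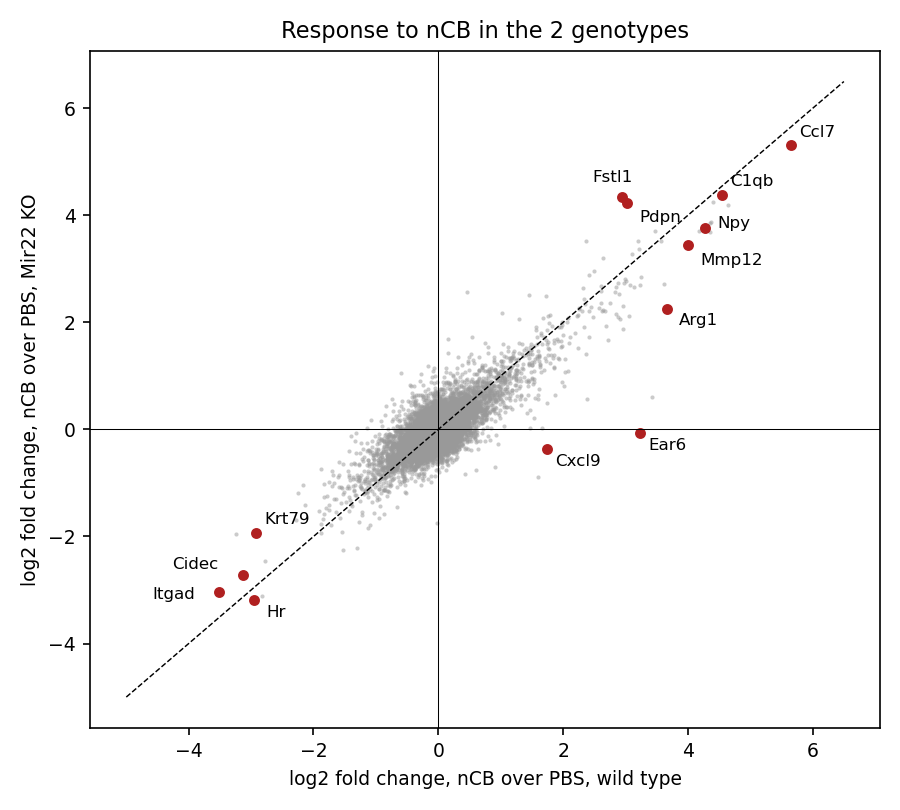
Each point is 1 of 12380 features, placed by its log2 difference between nCB and PBS in wild-type samples (horizontal axis) and in knockout samples (vertical axis), with 13 genes labelled and a dashed line where both are equal; fitted values are drawn also for genes undetected in a group, such as Npy, Arg1 and Ear6. Ccl7 and C1qb lie high on both axes, Cidec and Hr low on both, and Cxcl9 falls below the line.

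The third comparison asked what the loss of Mir22 changed without carbon black. Tlcd2, the gene next to Mir22 on chromosome 11, was 6.56-fold higher in knockout cells (log2 2.71 ± 0.14, n = 3 per group, limma adjusted p = 2.85e-08), while none of the other 13 measured neighbours passed. Spint1, an inhibitor of membrane serine proteases, was 27.2-fold lower by the probe used (log2 −4.77 ± 0.10, adjusted p = 2.18e-13) and lower by −1.66 log2 units by its other probe. Supt16, a subunit of the histone chaperone FACT, was 8.80-fold lower, Pdpn 7.25-fold lower and Ang, a secreted ribonuclease, 6.85-fold lower by the probes used. The other detected probes of Supt16 (−0.20) and Ang (−0.16) did not follow, and neither did those of Plcb2 (0.16) and Pla2g4b (0.04), so a change of these transcripts as a whole is not shown. Arhgap22 (+1.94), Wdfy1 (+1.67), Cd93 (+1.37) and Fmr1 (+1.22) were higher. The groups did not overlap for 13.2% of features against 10% by chance.

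Of 12380 features, 51 were higher and 66 lower in knockout PBS samples. The counts fell to 30 and 39 without wild-type PBS 1, to 31 and 40 without knockout PBS 3, to 31 higher without knockout PBS 1 and to 42 lower without wild-type PBS 2. With median scaling, which moved the median of all features by −0.12 log2 units, 18 were higher. The calls lay close together on some chromosomes. Within 10 Mb of Mir22, 6 of 224 genes were called (2.68%) against 0.961% elsewhere (Fisher's exact test, p = 0.0247), and within 5 Mb 2.46% (Fisher's exact p = 0.123). Within 20 Mb, 10 of 348 were called (2.87%) against 0.932% elsewhere (Fisher's exact p = 0.00246). Under nCB the region held no clear excess, with 10 of 224 called within 10 Mb (4.46%) against 3.26% elsewhere (Fisher's exact p = 0.338). Spint1, Bub1b, Plcb2, Pla2g4b and Lrrc57 belong to chromosome 2, and Supt16, Ang and Rnase6 to chromosome 14. Of genes called in both exposures, 20 of 761 tested lay on chromosome 2 (2.63%), 13 of 334 on chromosome 14 (3.89%) and 6 of 854 on chromosome 11 (0.703%), against 20 of 7844 on all others (0.255%).

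Genes of MHC class II presentation were lower in knockout PBS samples. Of 12 measured, 3 were lower over all features (Ciita −0.74, H2-Ab1 −0.78, H2-Eb1 −0.73) and 9 adjusted over the list alone (median −0.58, list adjusted p = 6.48e-10). With an estimated correlation the adjusted p was 0.197. All 3 single calls depended on single arrays: Ciita was lost in 4 of the 12 models that left out 1 array, H2-Ab1 in 8 and H2-Eb1 in 10. Ciita had adjusted p = 0.113 without wild-type PBS 1, 0.0691 without wild-type PBS 2, 0.0572 without knockout PBS 2 and 0.104 without knockout PBS 3. H2-Ab1 had 0.101, 0.198, 0.0865, 0.169 and 0.152 without wild-type PBS 1, 2 and 3 and knockout PBS 1 and 3, and 0.0555, 0.0599 and 0.0526 without wild-type nCB 1, 2 and 3. H2-Eb1 had 0.208, 0.198, 0.0716, 0.190, 0.107 and 0.0746 without wild-type PBS 1, 2 and 3 and knockout PBS 1, 2 and 3, and 0.0640, 0.0730, 0.0526 and 0.0588 without wild-type nCB 1, 2 and 3 and knockout nCB 2.

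Markers of several cell types moved with the class II genes in knockout PBS samples. Conventional dendritic cell markers were lower in 1 of 15 over all features, Mgl2 (−0.75), and 5 over the list alone (median −0.35, list adjusted p = 1.88e-05, and adjusted p = 0.231 with an estimated correlation). The call for Mgl2 was lost in 7 of the 12 models that left out 1 array (wild-type PBS 1, 2 or 3, knockout PBS 1 or 3, wild-type nCB 1 or 2; highest adjusted p = 0.206). B cell markers were lower in 0 of 8 (2 over the list alone; list adjusted p = 0.00177), monocyte markers in 0 of 14 (2 over the list alone; list adjusted p = 0.00210) and neutrophil markers in 0 of 12 (1 over the list alone; list adjusted p = 0.00195). With an estimated correlation all 3 lists had adjusted p = 0.197. Neutrophil chemoattractants shifted the other way, with 0 of 5 called over all features and 2 higher over the list alone, Cxcl2 (+1.43, adjusted p over all features 0.0613) and Cxcl1 (+0.96, 0.0642; list adjusted p = 0.00279, and adjusted p = 0.197 with an estimated correlation). Cxcl1 averaged 4.40 log2 in wild-type PBS samples, below the lowest detected intensities there (4.51 to 4.58), so its size rests in part on background. Cell cycle genes shifted down with 1 of 22 called by either adjustment, Bub1b of chromosome 2 (list adjusted p = 0.00210, and adjusted p = 0.197 with an estimated correlation). Without knockout PBS 2 the call for Bub1b was lost (adjusted p = 0.0543). The heat shock list shifted up with 0 of 14 called (2 over the list alone; list adjusted p = 0.0386, and adjusted p = 0.197 with an estimated correlation). It was lost without wild-type PBS 1 (0.162), knockout PBS 1 (0.116) or knockout PBS 2 (0.141), and with the values of the authors (0.0837). None of 13 published targets of miR-22 passed (list adjusted p = 0.838), nor did any of 14 histone deacetylases and sirtuins (list adjusted p = 0.837), with Hdac4 at −0.51 ± 0.16 (adjusted p = 0.242). At an unadjusted limma p under 0.05, 1025 of 12380 features passed in this comparison, where a share of 0.05 would pass by chance. After adjustment 117 passed.

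**Figure D2:**
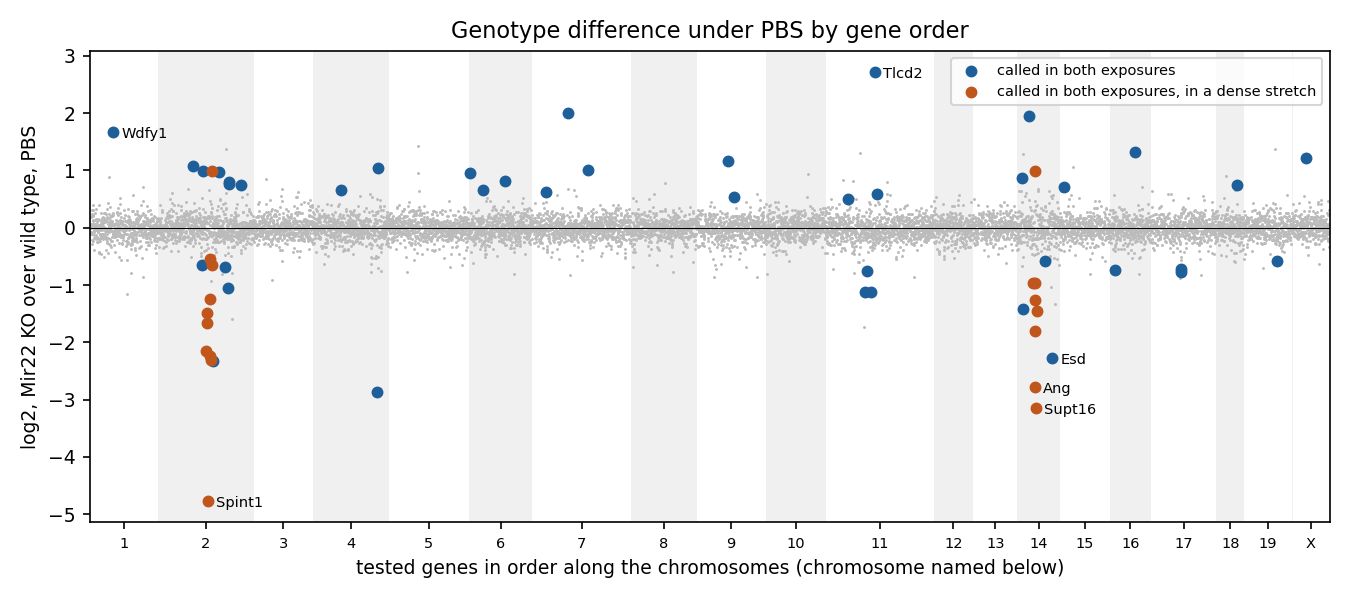
Log2 difference between knockout and wild type under PBS (vertical axis) of tested genes in their order along all chromosomes (horizontal axis). Grey points were not called in both exposures. Blue points were called in both exposures, and orange points are those of them that lie in a dense stretch. The orange stretch of chromosome 2 holds 10 called genes among 59 tested, that of chromosome 14 holds 8 among 43.

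The fourth comparison asked how knockout and wild-type cells differed after carbon black. Ear6, a ribonuclease of the eosinophil-associated family, was undetected in knockout nCB samples and at least 20.1-fold lower; its paralogs are close in sequence, so the member measured is uncertain. Tlcd2 was 10.3-fold higher (log2 3.36 ± 0.14, n = 3 per group, limma adjusted p = 1.45e-09) and Spint1 22.3-fold lower by the probe used (log2 −4.48 ± 0.10; −2.08 by its other probe). Cxcl9, a chemokine induced by interferon gamma, was lower (log2 −1.48 ± 0.20), as was Arg1, the arginase of alternatively activated macrophages (−1.40). Fstl1 (+1.56 ± 0.26), Pdk4, a kinase that restrains pyruvate oxidation (+1.49), and Krt79 (+1.34) were higher. Of 12380 features, 239 were higher and 185 lower, and the groups did not overlap for 19.8% of features against 10% by chance.

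Interferon response genes were lower in knockout nCB samples. Of 19 measured, 8 were lower and none higher (12 and 0 adjusted over the list alone; median −0.63, list adjusted p = 1.65e-12, and adjusted p = 0.0575 with an estimated correlation). Ifi205 differed by −1.31, Ifit2 by −1.17, Cxcl10 by −1.10 ± 0.14 and Ifit3 by −0.95. MHC class II genes were lower in 7 of 12 and higher in none (10 and 0 over the list alone; median −0.69, list adjusted p = 3.31e-10, and adjusted p = 0.231 with an estimated correlation), with H2-DMb1 at −0.75 and H2-Eb1 at −0.83. Knockout nCB 3 stood apart, with a list mean of 9.13 against 8.72 and 8.71 on the other knockout nCB arrays and 9.34 to 9.56 in wild type. H2-Eb1 was lost without wild-type nCB 1 (adjusted p = 0.0565) or knockout nCB 2 (0.0739). Other chemokines were lower in 6 of 16 and higher in none (8 and 0 over the list alone; list adjusted p = 2.04e-05, and adjusted p = 0.259 with an estimated correlation), with Cxcl9, Ccl8 (at least 1.52-fold) and Ccl17 (−0.92 ± 0.20, adjusted p = 0.0206). The call for Ccl17 was lost without wild-type nCB 1 (adjusted p = 0.101), knockout nCB 1 (0.0761) or knockout nCB 2 (0.121). With the values of the authors Ifi205, Ifit2, Cxcl10, Ifit3 and Fstl1 were no longer called (adjusted p = 0.247, 0.108, 0.0614, 0.0599 and 0.421).

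Cell type markers moved with these groups in knockout nCB samples. Monocyte and interstitial macrophage markers were lower in 5 of 14 by either adjustment (list adjusted p = 3.33e-04, and adjusted p = 0.258 with an estimated correlation), with C1qa at −1.02, lost with the values of the authors (adjusted p = 0.237), and Fcgr1 at −0.61, lost with median scaling (0.210). Alveolar macrophage markers were higher in 3 of 14 (7 over the list alone; list adjusted p = 1.11e-04, and adjusted p = 0.259 with an estimated correlation), with Krt79, and with Il18 (+0.72), whose call was lost with median scaling (adjusted p = 0.386) and whose other probe did not follow (−0.21). Dendritic cell markers were lower in 2 of 15 (4 over the list alone; list adjusted p = 0.00102, and adjusted p = 0.480 with an estimated correlation). Knockout nCB 3, with a list mean of 6.42, lay among the wild-type nCB samples (lowest 6.33), so this shift rested on knockout nCB 1 and 2 (5.97 and 5.93). The same array was the highest of its group for B cell, T cell, neutrophil and erythroid markers. Cell cycle genes were lower in 2 of 22 by either adjustment, Bub1b (−1.44) and Tyms (−0.53). Tyms was lost without wild-type nCB 1 (0.0908), wild-type nCB 3 (0.0876) or knockout nCB 2 (0.159), and 1 of its 2 further probes did not follow (0.01). Their list adjusted p was 0.0281, and the adjusted p was 0.305 with an estimated correlation. This shift was lost with median scaling (0.0592), without wild-type nCB 3 (0.122) and without knockout nCB 3 (0.122).

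**Figure D3:**
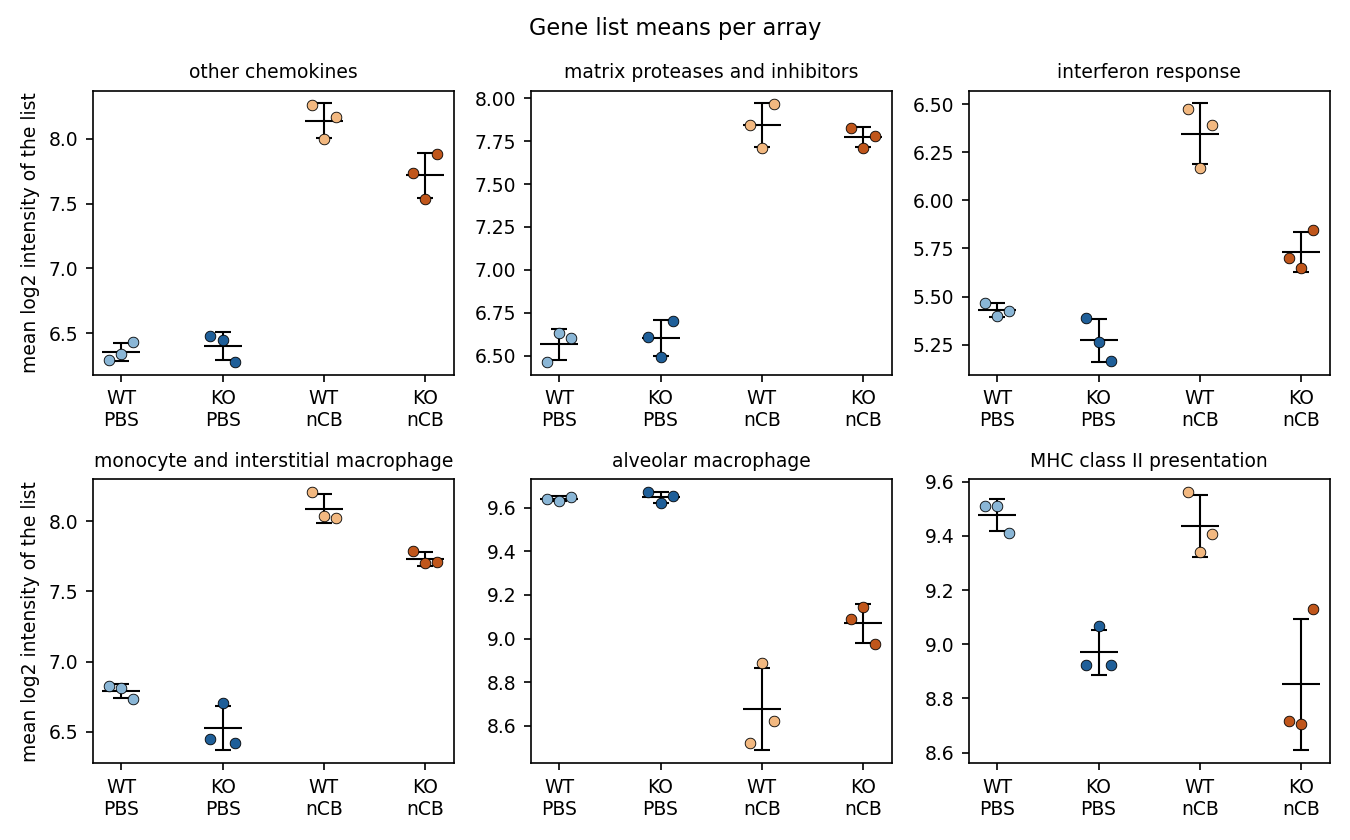
Mean log2 intensity of 6 gene lists (vertical axis, its own range in each panel and not starting at 0) on each of 12 arrays, grouped by genotype and exposure; points are arrays and bars are the mean and SD of 3. The interferon panel separates wild-type from knockout samples under nCB, where the median member differed by −0.63, and the alveolar panel falls with nCB.

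Of 13 published targets of miR-22, 2 were higher in knockout nCB samples, Hdac4 and Purb (+0.79, lost with median scaling, adjusted p = 0.244), and none lower (2 and 1 over the list alone; list adjusted p = 0.593). Hdac4 differed by +0.68 ± 0.16 (adjusted p = 0.0288). This call was lost without wild-type nCB 1, 2 or 3 (adjusted p = 0.0830, 0.0774 and 0.0764), without knockout nCB 1 or 2 (0.0733 and 0.161), with median scaling (0.335), the values of the authors (0.101), no detection filter (0.101) and only the compared groups (0.0521). The other measured deacetylases and sirtuins did not pass (list adjusted p = 0.933, with a median of −0.03 and a mean of 0.03). Among genes named in advance, Jun (−0.22), Fos (−0.14), Il1b (−0.05), Mmp12 (−0.24), Cxcl1 (−0.03) and Hmox1 (−0.22) did not pass. The counts fell to 102 higher and 89 lower without wild-type nCB 1, to 85 and 75 without knockout nCB 2 and to 148 higher without knockout nCB 1. They were 38 and 81 with median scaling and 81 and 59 with the values of the authors.

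Both comparisons of genotype shared 34 features called higher (0.985 expected for independent calls) and 35 called lower (0.986 expected), with 1 in opposite directions. Across all features their differences correlated at r = 0.34 and rho = 0.13.

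The fifth comparison asked whether the nCB effect itself differed between genotypes. Cxcl9 responded less to nCB in knockout than in wild-type cells, and Arg1 and Cxcl10 reached lower levels there. Arg1, undetected in PBS samples of both genotypes, reached a log2 intensity of 7.93 in wild-type and 6.52 in knockout nCB samples (n = 3 per group, limma interaction adjusted p = 0.00210). Cxcl9 went from 5.90 to 7.65 in wild-type cells and from 6.54 to 6.17 in knockout cells (interaction −2.11 ± 0.28, adjusted p = 0.00381). Ear6 went from 5.64 to 8.88 in wild-type cells and was undetected in knockout cells under both exposures (interaction adjusted p = 7.81e-04), as was Rnase2b, which went from 5.19 to 6.85 in wild-type cells. An effect of nCB on either gene in knockout cells was therefore not measurable, and neither was the size of its difference between genotypes. Both lie in the dense stretch of chromosome 14.

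In all, 16 features passed the interaction test, 5 positive and 11 negative. Neat1, a nuclear long noncoding RNA (+1.28 ± 0.21, adjusted p = 0.0252), Cldn23, a claudin, Flt1, a receptor of vascular growth factors (+1.06), Sorl1 (+0.96) and Ripor2 (+0.93) were positive. Of 4 further probes of Ripor2, 3 did not follow (0.05, 0.23 and −0.03). Gpr171 (−1.61), Klk1b11 (−1.37), Gpr176, Ndrg1 (−1.25), Cxcl10 and Gm4951 were negative. Like Arg1, Cldn23, Gpr176 and Cxcl10 were undetected in PBS samples of both genotypes, so for these 4 the change from PBS was not measurable and their calls rest on levels in nCB samples. In all, 6 of the 16 had such a pair of undetected groups, and Gm4951 was undetected in wild-type PBS samples. The interaction for Hdac4 was +1.19 ± 0.23 and did not pass (adjusted p = 0.0544; 0.0170 to 0.374 over the alternatives). Its log2 intensity was 6.13 and 5.74 in wild-type PBS and nCB samples and 5.62 and 6.42 in knockout samples. Counts by array left out were 1 positive and 7 negative without wild-type PBS 1, wild-type PBS 2, knockout PBS 1, knockout PBS 2 or wild-type nCB 1, and 0 and 6 without knockout PBS 3. Positive counts were 3 without wild-type PBS 3 or wild-type nCB 3, 1 without knockout nCB 1, 11 without wild-type nCB 2 and 19 without knockout nCB 3. Calls by gene were lost in 11 of the 12 models without 1 array for Ripor2 and Ndrg1, 10 for Flt1, Sorl1, Cxcl10 and Gm4951, 8 for Neat1 and Gpr171, 4 for Klk1b11 and 1 for Cldn23 (without knockout PBS 3, adjusted p = 0.0566), and in 0 for Ear6, Rnase2b, Arg1, Cxcl9 and Gpr176. With the values of the authors only 3 of the 16 stayed called, among them Ear6 and Gm4951, while Arg1 (adjusted p = 0.192), Cxcl9 (0.0794), Rnase2b (0.0628) and all other named genes were lost. With median scaling 6 of the 16 stayed called.

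Gene lists shifted in the interaction as well. Interferon response genes were negative in 1 of 19 over all features, Cxcl10, and in 7 over the list alone (median −0.40, or −0.36 without Cxcl10; list adjusted p = 2.86e-07, and adjusted p = 0.262 with an estimated correlation). Other chemokines were negative in 2 of 16 and 4 over the list alone (list adjusted p = 6.49e-06, and adjusted p = 0.310 with an estimated correlation). Their median was −0.37, and −0.20 without 4 members undetected in a pair of groups. Alveolar macrophage markers were positive in 0 of 14 and 4 over the list alone (median 0.41, list adjusted p = 0.00131, and adjusted p = 0.310 with an estimated correlation). The 2 probes of Il18 differed in sign in the interaction (+0.65 and −0.68). MHC class II genes did not shift in the interaction (median −0.15, list adjusted p = 0.362), and neither did published miR-22 targets (list adjusted p = 0.683).

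**Figure D4:**
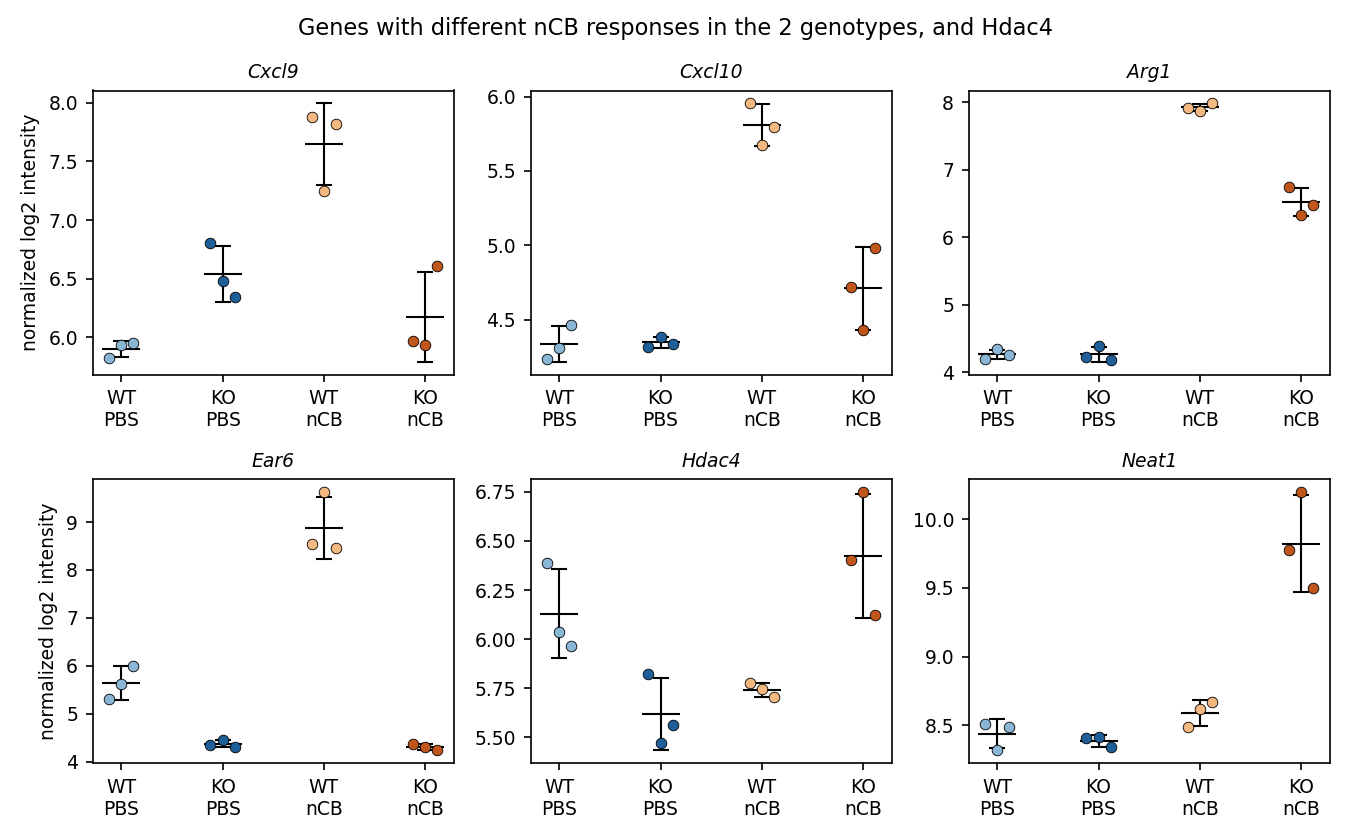
Log2 intensity (vertical axis) of Cxcl9, Cxcl10, Arg1, Ear6, Hdac4 and Neat1 on each of 12 arrays, grouped by genotype and exposure; points are arrays and bars are the mean and SD of 3. Ear6 reaches 8.88 only in wild-type nCB samples, and Arg1 reaches 7.93 there against 6.52 in knockout nCB samples.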

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

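Tests chosen only after the result was seen were the windows of neighbouring genes, the direction of calls in the stretches, the level of Irf9, and both tests of the cell types behind the nCB response; the test on further probes, the adjustment for cell type markers and the regroupings were chosen before.

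The interaction test called 16 features. Among those detected in every group, negative values were −2.82 for a probe without a gene symbol, −2.11 for Cxcl9, −1.61 for Gpr171, −1.37 for Klk1b11 and −1.25 for Ndrg1, and positive values were 1.28 for Neat1, 1.06 for Flt1, 0.96 for Sorl1 and 0.93 for Ripor2. The others rest in part on signals not above background, so their fitted values are no measure of a difference of folds: −3.31 for Ear6 and −1.62 for Rnase2b, undetected in knockout samples under both exposures, −1.41 for Arg1, −1.33 for Gpr176, 1.19 for Cldn23 and −1.11 for Cxcl10, undetected in PBS samples of both genotypes, and −0.996 for Gm4951, undetected in wild-type PBS samples. List medians that differed were −0.40 for interferon response, −0.37 for other chemokines, 0.41 for alveolar macrophage markers, −0.27 for the heat shock and dissociation list and 0.45 for B cell markers; the median of other chemokines was −0.22 without knockout nCB 2. Each of the 5 lists was lost with an estimated correlation (adjusted p = 0.262, 0.310, 0.310, 0.270 and 0.310). The heat shock list (list adjusted p = 0.00957) was also lost without wild-type PBS 1 (0.0508) or wild-type nCB 3 (0.0847). The B cell list (0.0139) was lost without wild-type PBS 1 (0.0809), knockout PBS 1 (0.0701), wild-type nCB 3 (0.103) or knockout nCB 3 (0.149).

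Regrouping the genotype labels within each exposure gave as many interaction calls as the real 16 in 3 of 100 drawn regroupings, the real one included. The highest other gave 29 and the second highest 17. Such regroupings also turn a genotype difference shared by both exposures into interaction calls. They are therefore no clean reference for chance, which they do not exclude. Exchanging the genotype labels under PBS alone, which was not among those drawn, gave 399 calls, which points to a genotype structure shared by both exposures. For each comparison of 3 arrays against 3, the 10 splits are too few for a share under 0.05. Every other split also mixes arrays of both groups, so a real difference becomes spread within groups and lowers its calls. Low counts in other splits therefore neither show nor exclude chance. The real split was the 1 with as many calls each time: 2240 against at most 0 in other splits for nCB in wild type, 1978 against at most 1 for nCB in knockout cells, 117 against at most 0 for genotype under PBS and 424 against at most 1 for genotype under nCB.

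Genes called between knockout and wild type in both exposures lay next to each other, in stretches of chromosome 2 (10 of 59 tested) and chromosome 14 (8 of 43). The loss of miR-22 alone stays open. The densest window of 21 genes held 6 calls against 3 at the 95th percentile of shuffled positions (permutation p = 2.00e-04). The 59 genes of smallest p for nCB in wild-type cells exceeded it too (4 against 3, permutation p = 0.0130). Neighbouring chemokine genes alone can thus exceed that percentile, but they do not show that coregulation yields windows with 6 calls. Off the chromosome of Mir22, 55 overlapping windows in 2 stretches exceeded that percentile. The nCB genes had 3 such windows, all on chromosome 11 in a stretch with Ccl2, Ccl7, Ccl12 and Ccl9. Chromosome 11 is that of Mir22, so their count of 0 elsewhere is a weak reference. DNA of another strain or line around these loci in the knockout mice is a candidate explanation. In the stretches 2 calls were higher and 16 lower, against 26 and 15 outside (Fisher's exact p = 2.10e-04). That test treats neighbouring calls as independent, which they need not be, so its p-value can be too small. Ang, Rnase6, Rnase2b and Ear6, ribonuclease genes, follow each other among the calls of the chromosome 14 stretch. Sequence variants under single probes stay open: 25% of the further probes of these genes (3 of 12) moved the same way, against 31.8% elsewhere (Fisher's exact p = 1.00), too few to decide. Genes called elsewhere are also no clean reference, since they include others on chromosomes 2 and 14, and Tlcd2 beside Mir22. A regulatory effect of the deletion on distant genes was not tested.

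Interferon response genes were lower in knockout than in wild-type nCB samples, with a mean difference of −0.62 (95% interval −0.82 to −0.41). Irf9, a factor of interferon signalling that was chosen after its values were seen, lies on chromosome 14. By the probe used it differed by 0.046 under PBS (−0.21 to 0.30) and by −0.68 under nCB. By its other probe it differed by −0.16 under PBS and by −0.84 under nCB. A segment of the knockout line that lowers Irf9 equally under both exposures was therefore argued against. With nCB, Irf9 changed by 0.62 in wild-type and −0.10 in knockout cells by the probe used. A segment that lowers Irf9 only under nCB stays open, since PBS samples cannot show such an effect. Fewer monocyte-like cells relative to alveolar macrophages may contribute, since the difference of those marker lists was itself lower by −0.75 (−1.07 to −0.43) and the interferon difference became −0.31 (−0.68 to 0.07) with it as a covariate. Its interval then held 0 as well as sizes near the first value, so this and a weaker interferon response of each cell cannot be told apart. Of the measured list members, 1 of 14 monocyte, 4 of 14 alveolar and 1 of 19 interferon genes also stood in another list.

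Alveolar macrophage markers fell and C1q rose with nCB in wild-type samples, the former with an adjusted p of 0.052 for the list with an estimated correlation. A lower share of alveolar macrophages alone would raise markers of every other cell type alike. This holds only if alveolar macrophages lack those markers and their signals lie well above background. Neither condition was tested, so the explanation was argued against only where both hold. Monocyte markers rose more than B cell markers by 1.86 ± 0.17 (1.06 to 2.65), but the monocyte list holds the C1q genes of the pattern itself. Dendritic cell markers, a list without C1q, also rose more than B cell markers, by 1.17 ± 0.11 (0.63 to 1.72). Both gaps rest in part on the fall of B cell markers, a list shift lost without wild-type PBS 1 or wild-type nCB 3. In 13 of 36 pairs of other cell types the interval lay above 0. The pair of monocyte and B cell markers was picked as the one apart by most SEs. The widest gap, monocyte over erythroid markers, had an interval from −2.27 to 6.05. Arrival of monocytes or interstitial macrophages, some of which carry CD11c and would pass the isolation, is a candidate explanation: C1qb rose from a log2 intensity of 6.66 to 11.19 and Apoe from 8.21 to 10.32, and without the C1q genes the monocyte list still had a median of 0.24, with 5 of 11 members higher and none lower (camera p = 0.00109, and 0.0277 with an estimated correlation). A change of state within alveolar macrophages stays open and was not tested.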

How the results depend on the processing

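Tests that left out chromosomes 2, 11 and 14, and list tests with median scaling or the values of the authors, were chosen after seeing the data; the other tests were planned. No named gene or list called as reported changed sign, but the balance of calls did turn: the higher share went from 56.4% to 31.9% for genotype under nCB with median scaling, from 43.6% to 54.8% for genotype under PBS without chromosomes 2, 11 and 14, from 49.1% to 64.6% for nCB in wild-type cells with a minimum of 1 log2 unit, and from 31.2% to 55.9% positive for the interaction without knockout nCB 3. Median scaling moved most counts: nCB raised 531 and lowered 754 features in wild-type cells and raised 497 and lowered 300 in knockout cells, genotype raised 18 under PBS and raised 38 and lowered 81 under nCB, and the interaction was positive in 0 and negative in 6. With the values of the authors, genotype raised 30 under PBS and raised 81 and lowered 59 under nCB, the interaction was positive in 2 and negative in 4, and the correlation of both nCB effects was 0.63. Without a detection filter genotype raised 113 and lowered 108 under nCB and the interaction was negative in 5. With detection on all 12 arrays it was negative in 4, with all probes tested positive in 3, and with array weights positive in 13. With only the compared groups in the model genotype raised 141 under nCB. With a minimum of 1 log2 unit, nCB raised 314 and lowered 172 in wild-type and raised 284 and lowered 111 in knockout cells, genotype raised 18 and lowered 28 under PBS and raised 51 and lowered 36 under nCB, and the interaction was positive in 3, all fewer by construction. Without chromosomes 2, 11 and 14 genotype raised 23 and lowered 19 under PBS and lowered 121 under nCB. The replicate block, for which only 5 of 18 pairs of equal number correlated above 0.1, left the interaction positive in 2. Within 5 Mb of Mir22 2.46% of genes were called under PBS (Fisher's exact p = 0.123), and within 20 Mb 2.87% (Fisher's exact p = 0.00246). The cause of these changes was not tested.

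Leaving out 1 array at a time, nCB raised 852 to 1113 and lowered 816 to 1186 features in wild-type cells, and raised 806 to 1086 and lowered 647 to 910 in knockout cells. Genotype raised 30 to 56 and lowered 39 to 69 under PBS, and raised 85 to 322 and lowered 75 to 208 under nCB. The interaction was positive in 0 to 19 and negative in 6 to 15, and the correlation of both nCB effects ran from 0.75 to 0.81. The models without 1 array pool the spread over groups. Low signal over background limits genes near the detection level, such as Ccl7 in PBS samples. A slide block was not run, since the column names give no slide, and neither was the match to 8 bases of the microRNA seed, since no sequences were used here.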

Other observations

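No test in this part was chosen after its result was seen. Egr1, Fos and Dusp1 fell with nCB in both genotypes. The heat shock and dissociation list, which collects genes that also respond to tissue handling, fell in 5 of 14 measured in knockout cells and rose in none, by either adjustment (median −0.30, list adjusted p = 4.59e-04, and 0.0469 with an estimated correlation). Egr1 differed by −2.22, Fos by −1.84, Dusp1 by −1.79 and Ier2 by −1.44. In wild-type cells the list fell in 5 and rose in 1 and did not shift (6 and 1 over the list alone; list adjusted p = 0.132), with Egr1 at −1.30, Fos at −1.13 and Dusp1 at −1.10. AP-1 factors rose in 1 of 11 and fell in 3 in each genotype (2 and 5 over the list alone in wild-type cells, 2 and 3 in knockout cells), and the list did not pass (list adjusted p = 0.378 and 0.149). The riser, Atf3, changed by 1.01 in wild-type and 1.00 in knockout cells. Among cytokines that polarise TH17 cells and the IL-12 family, Il1a (+1.12 and +1.16 in wild-type and knockout cells) and Ebi3 (+0.81 and +1.10) rose and Il18 (−1.70 and −1.05; +0.08 and −0.60 by its other probe) fell by the probe used, and the list did not shift (list adjusted p = 0.986 and 0.507).

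In knockout cells nCB raised the p53, unfolded protein response and lipid-associated macrophage lists. The p53 list rose in 6 of 15 and fell in none (7 and 0 over the list alone; list adjusted p = 8.15e-05, and 0.0469 with an estimated correlation), and the unfolded protein response rose in 5 of 15 and fell in 1 (7 and 2 over the list alone; list adjusted p = 0.00280, and 0.0469 with an estimated correlation). Lipid-associated macrophage genes rose in 7 of 15 and fell in 1 (7 and 3 over the list alone; list adjusted p = 4.59e-04, and 0.0469 with an estimated correlation). Conventional dendritic cell markers rose in 5 of 15 and fell in none by either adjustment (list adjusted p = 1.45e-04, and adjusted p = 0.206 with an estimated correlation). NF-kB feedback genes rose in 4 of 15 and fell in 1 (7 and 1 over the list alone; list adjusted p = 0.0140, and adjusted p = 0.0851 with an estimated correlation). Glycolysis and hypoxia genes rose in 7 of 13 and fell in 3 by either adjustment (list adjusted p = 0.0190, and adjusted p = 0.127 with an estimated correlation). NRF2 targets rose in 3 of 14 and fell in 2 in knockout cells (4 and 2 over the list alone) and the list did not pass (list adjusted p = 0.149), and neither did metallothioneins (0.372) or cholesterol biosynthesis genes (0.821). Ribosomal protein genes (list adjusted p = 0.725 in wild-type and 0.372 in knockout cells) and mitochondrial respiration genes (0.882 and 0.383) did not shift with nCB; the latter had a median of 0.01 and a mean of −0.05 in wild-type cells. The surfactant protein gene Sftpd rose by 1.12 and 1.54 and Napsa fell, at −0.55 and −0.67, within an epithelial list that did not shift (0.929 and 0.819).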
